A study of Mus musculus with 8 samples.

How the data were processed

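RNA sequencing of whole liver was analysed from 8 mice that received a diet inducing non-alcoholic steatohepatitis (NASH) for 20 weeks, starting at 2 months of age. Of these, 4 were wild type (WT) and 4 were labelled as knockouts of E4bp4 in the liver (E4bp4-LKO). Per the labels, mRNA was enriched by oligo-dT selection or by depletion of ribosomal RNA, reverse transcription used random hexamers, and the amplified libraries were circularised. Which of the enrichment methods served which library, the strand, and the sex, strain and littermate status of the mice are not given in the sources used here. The submitters' notes name HISAT2 as the aligner. Its version, the quantification program, the genome build and the annotation release are not given in the sources used here, so no coordinates are reported.

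There was 1 deposited file per library, with values per Entrez gene and RefSeq transcript. The deposited column of expected counts holds estimated read or fragment counts per gene, without normalization, and 25.8% to 27.2% of its entries per library are fractional because reads were shared between transcripts or genes. The deposited FPKM column was normalized by the authors for effective transcript length and for the sum of estimated counts in the library. The lowest FPKM in each file was 0.01, and genes missing from a file were read as 0 for that library. The files together listed 16796 genes, of which 14119 stood in all 8 files. Isoform entries without a symbol were added to their gene by RefSeq accession for 26 entries, and 4 entries stayed without a name. No 2 libraries were copies of each other (lowest chi-square per degree of freedom between a pair, 8.11). Summed expected counts were 23805540 to 32290265 per library, so that 3 counts, taken as the detection floor, stood for 0.0929 to 0.126 CPM (counts scaled by the library total). Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

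Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and E4bp4-LKO was compared with WT by a two-sided quasi-likelihood test with robust dispersion (glmQLFit and glmQLFTest). Adjusted p values are Benjamini-Hochberg over the genes tested, with a threshold of 0.05, and they come from edgeR unless another tool is named. A positive log2 fold change means higher in E4bp4-LKO. Levels are TMM-normalized CPM, given as mean ± SD with n = 4 per group. The SE is that of the log2 fold change, derived as its absolute value divided by the square root of the quasi-likelihood F statistic. Principal components were taken from log2 CPM with a prior count of 2. Nfil3 was also compared by an exact two-sided permutation test.

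The comparison, its test, the 38 gene lists and the rule for naming genes were chosen before the data were examined. The rule named Nfil3, a panel of 9 fibrosis genes, the 10 genes with the largest rise and the 10 with the largest fall (adjusted p under 0.05, mean FPKM of at least 1, no overlap between the groups, no predicted gene models), and up to 4 members of each list with the smallest p. Genes named outside the rule are said to be so. Lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 37 lists that had tested members. Camera with an estimated correlation and directional fry were run beside it. Members passing the gene test were counted over all genes tested and also adjusted over the list alone. A list score per library is the mean over members of log2 CPM minus the mean of the 8 libraries.

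Alternatives chosen before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, a filter at 5 CPM in at least 4 libraries, voom with sample quality weights, limma with trend on log2(FPKM + 1) for genes at 1 FPKM or more in at least 4 libraries, the same with quantile normalization, on TPM and with a pseudocount of 0.1, thresholds of 0.1 or of a 2-fold change, and leaving out each mouse in turn. Library totals without TMM and a fit without WT mice 164 and 165 were added after the data had been seen. All 35 ways of dividing the 8 libraries into groups of 4 were also fitted. The tests were tried on simulated data: with 4 and 4 libraries at this depth, edgeR called 55.2% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 95.5% of those changed 4-fold, with 200 changed genes and 10 unchanged genes called. A simulated list of 21 members changed 1.5-fold was called by camera, and 0 other lists were. Genes were simulated independently of each other, whereas the estimated correlation within the matrix list was 0.61. The simulation therefore does not show how often camera calls correlated lists falsely, and the shares of genes called may differ in the real data.

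Gene Ontology terms in the deposited tables were tested for enrichment by a one-sided hypergeometric test with Benjamini-Hochberg adjustment, among 10190 annotated features that could have been called, over 1553 terms of 10 to 500 genes, with 22 Mup genes counted as 1 feature. This enrichment was chosen after the gene results had been seen. Neighbouring genes were taken from RefSeq for GRCm38.p6, in which 13228 of the 13244 tested genes were found by Entrez identifier. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 served for the remaining steps. Transcripts encoded by mitochondrial DNA and non-coding RNA were not listed in the files and could not be analysed here.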

Results

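The data were mRNA profiles of whole liver from 4 WT mice (164, 165, 166 and 167) and 4 E4bp4-LKO mice (143, 144, 145 and 179), all on the NASH diet. E4BP4, the product of Nfil3, is a transcriptional repressor that binds D-box elements and is best known from the circadian clock and from lymphocyte development. The title of the study places it in hepatocytes and in fibrosis through activation of hepatic stellate cells, the main collagen-producing cells of the liver. The comparison asks which liver genes differ between the groups under this diet. The strain of the mice and whether the groups were littermates are not given in the sources used here, so a difference in background is not separated from loss of E4bp4 in any result below. Libraries from mice on another diet were not used here. The WT libraries held 29871257, 30200874, 28477075 and 29060661 counts in the order of the mouse numbers given, and the E4bp4-LKO libraries 28066848, 32290265, 28778546 and 23805540.

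Nfil3 (Entrez Gene 18030) was lower in all 4 E4bp4-LKO livers than in any WT liver. WT libraries measured 11.4, 8.79, 12.1 and 16.5 CPM in mice 164 to 167, with a mean of 12.2 ± 3.20 (SD, n = 4). The E4bp4-LKO libraries measured 3.33, 6.22, 6.14 and 3.35 CPM in mice 143, 144, 145 and 179, with a mean of 4.76 ± 1.64 (SD, n = 4). The log2 fold change was -1.35 (SE 0.25, adjusted p = 0.0121), a 2.54-fold lower level. The exact permutation test gave p = 0.0286, the smallest p that the 70 arrangements allow. These values are from whole tissue, which also holds cells other than hepatocytes, and the files give no values per exon.

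Between E4bp4-LKO and WT livers, 1436 of 13244 genes tested changed, of which 578 rose and 858 fell, so 59.7% of the changed genes were lower. A change of at least 2-fold was seen for 120 higher and 249 lower genes. The 2 groups did not overlap for 2448 genes, 18.5% of those tested, where chance gives 2.86%. The first principal component held 52.7% of the variance and separated the groups, with WT scores of -49.3, -30.1, -11.1 and -10.4 for mice 164 to 167 and E4bp4-LKO scores of 19.2 to 31.2. The outer WT livers 164 and 165 also had the largest TMM factors, 1.16 and 1.09, against 0.94 to 1.00 in the other 6 libraries. With library totals in place of TMM the median log2 fold change of all genes shifted by -0.159, and 291 genes rose and 1660 fell (85.1% lower). The count depended on single mice: it was 506 without E4bp4-LKO 144, 633 without WT 165, 735 without E4bp4-LKO 145, 757 without E4bp4-LKO 179, 933 without WT 164, and 387 without WT 164 and 165 together.

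**Figure D1:**
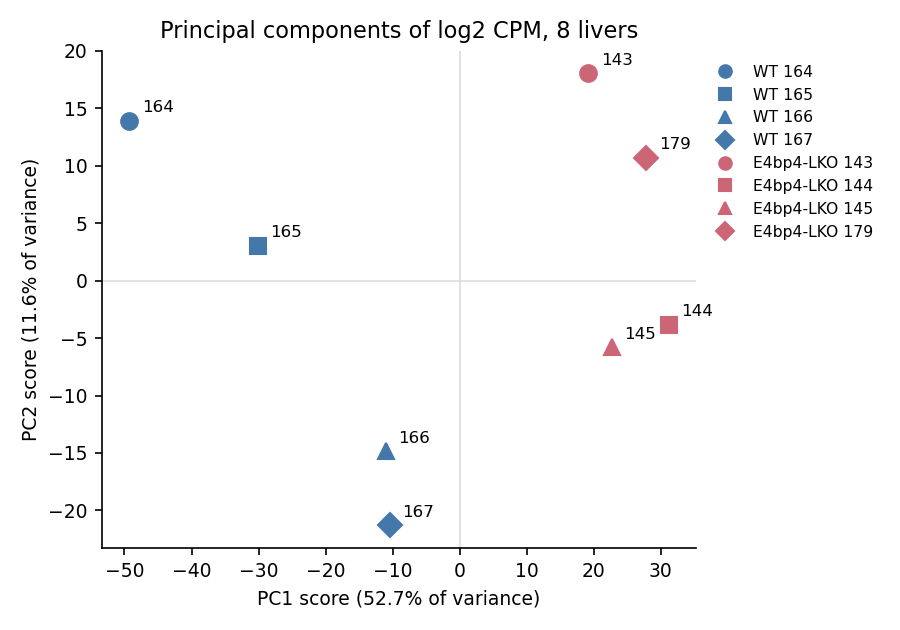
Scores of the 8 livers on the first principal component (horizontal, 52.7% of variance) and the second (vertical, 11.6%) of log2 CPM, with a point per library, coloured by group and numbered by mouse. All WT livers lie at or below -10.4 on the horizontal axis, with WT 164 farthest out at -49.3, and all E4bp4-LKO livers at or above 19.2.

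The genes with the largest rises belonged mainly to families that male mouse liver expresses strongly. Hsd3b5, a steroid-metabolising enzyme of male liver, rose from 0.134 ± 0.0815 to 20.5 ± 4.27 CPM (SD, n = 4; log2 fold change 7.27, SE 0.29, adjusted p = 7.89e-07). Slco1a1, an organic anion transporter, rose from 17.1 ± 10.8 to 273 ± 63.9 CPM (log2 fold change 4.01, SE 0.44, adjusted p = 0.00318). Of the major urinary proteins, Mup7 rose by a log2 fold change of 5.36 (adjusted p = 0.00551) and Mup14 by 4.46 (adjusted p = 0.00920). Mup1, Mup9, Mup11 and Mup15 also passed, with log2 fold changes of 4.07, 4.16, 4.54 and 6.03. The Mup genes share reads, so the level of each copy is uncertain, while their summed share of counts was 1.37% to 1.73% in WT and 2.85% to 4.45% in E4bp4-LKO. Nat8f7, of an N-acetyltransferase family, and the histone gene Hist1h2bj had log2 fold changes of 7.40 (adjusted p = 0.000149) and 5.24 (adjusted p = 0.00273). Their counts were fractional as well, and their WT levels of 0.138 ± 0.237 and 0.0750 ± 0.0371 CPM lay near 3 counts, as did that of Hsd3b5, so these fold changes are imprecise. Some of these calls were lost when 1 mouse was left out, which by itself weakens the test. Mup15 passed in none of the 8 such fits, whichever mouse was left out (adjusted p 0.0592 to 0.0950, log2 fold change 5.62 to 6.63). Mup9 passed only without E4bp4-LKO 145 (adjusted p up to 0.134). Mup11 did not pass without WT 166, E4bp4-LKO 144 or E4bp4-LKO 179 (up to 0.0609), and Mup1 did not without WT 165 (0.0501).

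Among the genes with the largest falls were cytochrome P450 genes of female liver and Cdkn1a, which encodes the cell-cycle inhibitor p21. Cyp2a4 fell from 43.4 ± 17.6 to 3.57 ± 2.10 CPM (SD, n = 4; log2 fold change -3.63, SE 0.49, adjusted p = 0.00606). Cyp2b9 fell from 41.0 ± 23.8 to 3.85 ± 4.24 CPM (log2 fold change -3.40, SE 0.78, adjusted p = 0.0385). Both had fractional counts. Ly6d, a surface antigen, fell from 115 ± 52.5 to 13.5 ± 7.53 CPM (log2 fold change -3.10, adjusted p = 0.0108), and Gipc2 from 7.31 ± 4.07 to 0.722 ± 0.248 CPM (log2 fold change -3.36, adjusted p = 0.00440). Cdkn1a fell from 48.1 ± 7.36 to 11.5 ± 4.2 CPM (log2 fold change -2.07, SE 0.23, adjusted p = 0.00181). The others were Tubb2b (-2.55), Lrtm2 (-2.36), Shc2 (-2.31), Fam83a (-2.16) and Pls1 (-2.16). Cyp2b9 passed only without E4bp4-LKO 145 among the fits without 1 mouse (adjusted p up to 0.0956). Tubb2b did not pass without E4bp4-LKO 144 or 145 (up to 0.0615), Lrtm2 without WT 164, 165 or 166 or E4bp4-LKO 143 or 144 (up to 0.0958), and Shc2 without WT 165 or E4bp4-LKO 143 or 144 (up to 0.0746).

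In the panel of fibrosis genes, 4 of 9 fell in E4bp4-LKO livers. Spp1, which encodes the secreted matricellular protein osteopontin, fell from 280 ± 126 to 82.8 ± 10.3 CPM (SD, n = 4; log2 fold change -1.76, SE 0.29, adjusted p = 0.00924). Timp1, an inhibitor of matrix metalloproteinases, fell from 4.82 ± 1.34 to 1.39 ± 0.256 CPM (log2 fold change -1.81, SE 0.23, adjusted p = 0.00183). The collagen genes Col3a1 and Col1a2 fell, Col3a1 from 249 ± 98.7 to 112 ± 24 CPM (log2 fold change -1.15, SE 0.26, adjusted p = 0.0246) and Col1a2 from 145 ± 70.7 to 59.4 ± 15.9 CPM (log2 fold change -1.29, SE 0.33, adjusted p = 0.0442). Col1a1 measured 197 ± 113 and 71.8 ± 25.5 CPM without overlap of the groups but did not pass (log2 fold change -1.46, SE 0.41, adjusted p = 0.0597). Acta2, the smooth muscle actin of activated stellate cells, measured 7.68 ± 1.75 in WT and 7.69 ± 0.686 CPM in E4bp4-LKO (log2 fold change 0.00, SE 0.16, adjusted p = 0.990), and its sign turned negative on FPKM, TPM and library totals. Tgfb1 (-0.31, adjusted p = 0.147), Pdgfrb (-0.62, adjusted p = 0.0883) and Des (-0.28, adjusted p = 0.210) did not pass either. Col1a1 passed without WT 166 (adjusted p = 0.0471) and in DESeq2. Col3a1 did not pass without WT 165 or E4bp4-LKO 143, 144 or 179 (up to 0.0746), nor did Col1a2 without WT 165, WT 167 or any of the E4bp4-LKO mice in turn (up to 0.113).

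**Figure D2:**
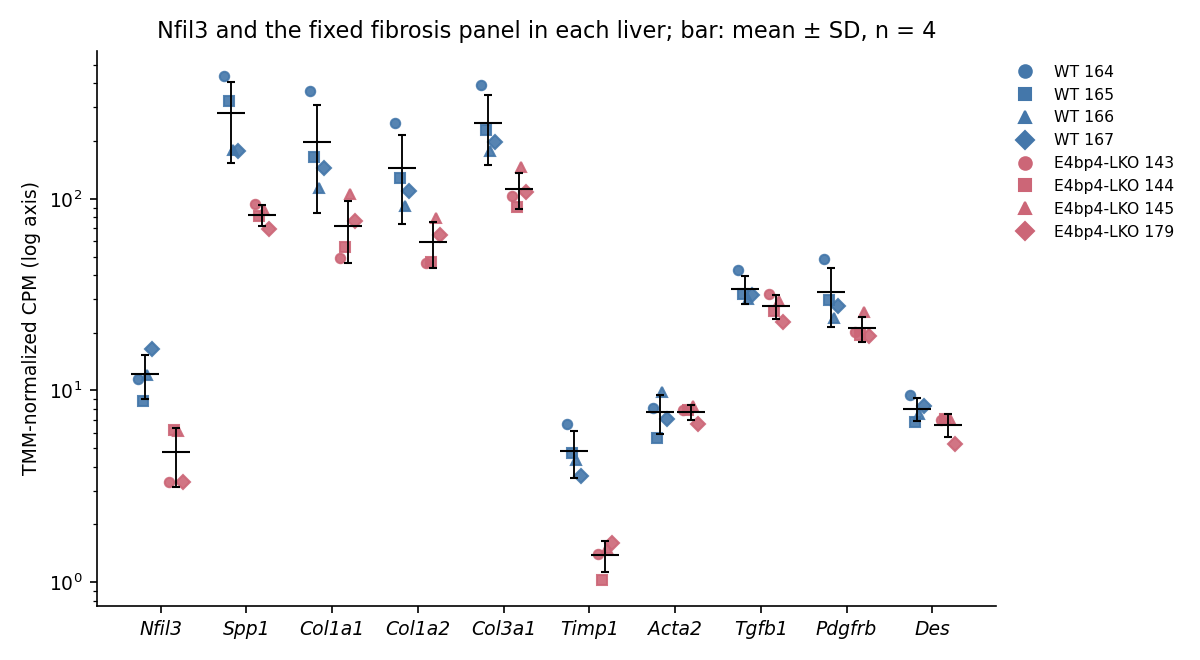
TMM-normalized CPM on a log axis of Nfil3 and the 9 fibrosis genes in each liver, with a point per library (4 WT, 4 E4bp4-LKO) and bars for mean ± SD. Nfil3, Spp1, Timp1 and the 3 collagen genes show no overlap between the groups, while Acta2 averages 7.68 CPM in WT and 7.69 CPM in E4bp4-LKO.

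Matrix genes fell in part. Of 32 genes for fibrillar and other matrix proteins, 16 fell, 1 rose and 15 did not pass (24 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.79. Sparc (-0.83, adjusted p = 0.0105), the proteoglycan gene Dcn (-0.55, adjusted p = 0.0112) and the collagen gene Col15a1 (-1.48, adjusted p = 0.0129) fell. Camera gave the list an adjusted p = 4.04e-09, and adjusted p = 0.356 with an estimated correlation. Of 14 proteases and inhibitors that remodel matrix, 5 fell, 0 rose and 9 did not pass (11 lower adjusted over the list alone), with a median of -0.74. They included the plasminogen activator Plat (-1.89, adjusted p = 0.00537), the urokinase receptor gene Plaur (-1.10, adjusted p = 0.00920) and the macrophage elastase Mmp12 (-1.82, adjusted p = 0.0121). That list had an adjusted p = 3.02e-06 by camera and adjusted p = 0.340 with an estimated correlation. Its median was -0.46 without WT 164, and its 5 lower genes became 2 without WT 164 and 165 together. WT 164 had the highest matrix score, 0.98, while the other end of the WT range, WT 166, lay at -0.02 and the E4bp4-LKO livers at -0.46 to -0.16. The 16 lower matrix genes became 3 without E4bp4-LKO 144, 4 without E4bp4-LKO 179, 5 without WT 165, 9 without E4bp4-LKO 143, and 4 without WT 164 and 165 together.

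Stellate cell genes were lower in part. Of 19 genes of activated stellate cells and myofibroblasts, 9 fell, 0 rose and 10 did not pass (11 lower and 1 higher adjusted over the list alone), with a median of -0.62. The receptor tyrosine kinase ligand Gas6 (57.3 ± 6.64 against 138 ± 22.7 CPM, log2 fold change -1.27, adjusted p = 0.000485), the tropomyosin gene Tpm1 (-0.70, adjusted p = 0.00436) and the collagen chaperone Serpinh1 (-0.92, adjusted p = 0.00473) fell, beside Timp1. The list had an adjusted p = 2.47e-05 by camera and adjusted p = 0.340 with an estimated correlation. Of 15 genes of quiescent stellate cells, 4 fell, 0 rose and 11 did not pass (7 lower adjusted over the list alone), with a median of -0.40 and 5 estimates above 0. Rgs5 fell (-0.75, adjusted p = 0.0128), and so did Cygb (-0.92, adjusted p = 0.0237) and Lrat, which stores retinol as esters (-0.40, adjusted p = 0.0362). That list had an adjusted p = 0.0140 by camera, adjusted p = 0.356 with an estimated correlation, and adjusted p = 0.104 on library totals. WT 164 had the highest score for both lists, 0.57 and 0.26. The 4 lower quiescent genes became 2 without WT 164 and 1 without WT 165, E4bp4-LKO 144 or E4bp4-LKO 179. Cygb did not pass without WT 165, E4bp4-LKO 144 or E4bp4-LKO 179 (adjusted p up to 0.0680), nor Lrat without WT 164, WT 165 or E4bp4-LKO 144, 145 or 179 (up to 0.106).

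Signals that act on stellate cells were mixed. Of 20 secreted stellate-activating factors, 6 fell, 1 rose and 13 did not pass (7 lower and 2 higher adjusted over the list alone), with a median of -0.32. The stress cytokine Gdf15 (-1.37, adjusted p = 0.00474), galectin-3 gene Lgals3 (-1.76, adjusted p = 0.00576) and the monocyte chemoattractant Ccl2 (-1.25, adjusted p = 0.0111) fell together with Spp1. The member that rose was Vegfa, an angiogenic factor, with a log2 fold change of 0.40 (adjusted p = 0.0260). It was named after its values were seen and did not pass without WT 165 or E4bp4-LKO 144 (up to 0.0780). The list had an adjusted p = 0.00366 by camera, adjusted p = 0.356 with an estimated correlation, and adjusted p = 0.0783 on library totals, and its median was -0.14 without WT 164. The TGF-beta signalling list did not pass (adjusted p = 0.147 by camera; adjusted p = 0.774 with an estimated correlation), with 4 of 22 lower, 1 higher and 17 not passing (6 lower and 1 higher adjusted over the list alone). Its median was -0.06 and turned to 0.03 with quantile-normalized FPKM and to 0.13 without WT 164 and 165, while without 1 mouse it ran from -0.13 (E4bp4-LKO 143 left out) to -0.01 (WT 164 left out). Within it the ligand Tgfb3 fell (-1.24, adjusted p = 0.0142). The count of 4 lower became 1 without E4bp4-LKO 179 and 2 without WT 164, WT 165 or E4bp4-LKO 143, 144 or 145, and the 1 higher became 0 without WT 165, E4bp4-LKO 145 or E4bp4-LKO 179. The 1 higher secreted factor became 0 without WT 165 or E4bp4-LKO 144 and 2 without WT 167.

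Macrophage genes fell in part. Of 13 genes of lipid-associated macrophages, 10 fell, 0 rose and 3 did not pass (10 lower adjusted over the list alone), with a median of -1.21. Trem2, a lipid-sensing receptor, fell from 11.2 ± 5.09 to 3.44 ± 0.859 CPM (SD, n = 4; log2 fold change -1.71, SE 0.31, adjusted p = 0.0114), and the lysosomal gene Cd63 from 43.8 ± 18.4 to 13.6 ± 2.01 CPM (log2 fold change -1.69, SE 0.29, adjusted p = 0.0113). Lgals3 and Spp1, named above, belong to this list too, and neither they nor Cd63 are specific to macrophages. The list had an adjusted p = 4.97e-07 by camera and adjusted p = 0.340 with an estimated correlation. Of 17 general macrophage and Kupffer cell genes, 6 fell, 0 rose and 11 did not pass (7 lower and 1 higher adjusted over the list alone), with a median of -0.35, a mean of -0.12 and scores that overlapped (WT -0.10 to 0.22, E4bp4-LKO -0.33 to 0.23). The complement genes C1qa (-0.56), C1qb (-0.63) and C1qc (-0.56) fell, and so did Cd5l (-0.56), with adjusted p between 0.00606 and 0.0123. Timd4, a gene of resident Kupffer cells, had a log2 fold change of 1.16 (adjusted p = 0.0809, and 0.04997 without WT 164, where it passed) and was named after its values were seen. This list had an adjusted p = 0.00441 by camera, adjusted p = 0.426 with an estimated correlation, adjusted p = 0.0538 by fry and adjusted p = 0.149 on library totals. WT 164 had the highest lipid-associated macrophage score, 0.98. The 10 lower genes of that list became 5 without E4bp4-LKO 144 or 179 and 6 without WT 165 or E4bp4-LKO 145, and the 0 Kupffer genes that rose became 1 without WT 164.

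Among lists of other immune cells, no shift was called for T and NK cells, B and plasma cells or dendritic cells. Of 15 T and NK cell genes, 0 rose, 0 fell and 15 did not pass (0 adjusted over the list alone), and the median of 0.05 turned negative on FPKM, TPM, quantile-normalized FPKM and library totals and without WT 167 (-0.04) or E4bp4-LKO 179 (-0.07), and was up to 0.16 without E4bp4-LKO 144 (adjusted p = 0.702 by camera, adjusted p = 0.923 with an estimated correlation). Cd4 had the smallest p in it (log2 fold change 0.72, adjusted p = 0.0689). Of 8 B and plasma cell genes, Jchain rose (1.95, adjusted p = 0.0239), the antigen-presentation genes Cd74 (-0.90, adjusted p = 0.0296) and H2-Aa (-0.97, adjusted p = 0.0317) fell, and 5 did not pass (1 higher and 2 lower adjusted over the list alone). The mean of that list was 0.08 and its median -0.05 (-0.18 without WT 167, -0.17 without E4bp4-LKO 143, -0.08 without E4bp4-LKO 179, -0.03 without WT 165, 0.01 without E4bp4-LKO 144 and 0.10 without WT 164), and camera did not call it (adjusted p = 0.784; adjusted p = 0.960 with an estimated correlation), though with a filter at 5 CPM its adjusted p was 0.0243. Irf8 (-0.68, adjusted p = 0.0143) was the 1 of 10 dendritic cell genes that fell, with 0 higher and 9 not passing (1 lower adjusted over the list alone; median -0.12, adjusted p = 0.394; adjusted p = 0.715 with an estimated correlation). The dendritic cell median ran from -0.34 without E4bp4-LKO 145, -0.23 without WT 166, -0.21 without E4bp4-LKO 143 and -0.19 without WT 167 to -0.08 without WT 164, -0.06 without WT 165 and -0.05 without E4bp4-LKO 179. Jchain did not pass without WT 165, WT 166 or E4bp4-LKO 144 (adjusted p up to 0.0697), Cd74 and H2-Aa without WT 165 or E4bp4-LKO 143, 144 or 179 (up to 0.0895), and Irf8 without E4bp4-LKO 144 (0.0533).

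Inflammatory genes fell in part. Of 10 monocyte and neutrophil genes, 2 fell, 0 rose and 8 did not pass (2 lower adjusted over the list alone), among them Plac8 (-0.82, adjusted p = 0.0166), with a median of -0.35. Camera gave an adjusted p = 0.0370, and adjusted p = 0.602 with an estimated correlation. The call ended on library totals (0.241), on quantile-normalized FPKM (0.0783), in fry (0.245) and without WT 164 (0.125), WT 165 (0.0755) or E4bp4-LKO 144 (0.0585), 145 (0.0874) or 179 (0.106), and in the latter 5 fits 1 gene fell. The median was -0.20 without WT 164 and -0.66 without E4bp4-LKO 143. Of 19 cytokine and chemokine genes, 5 fell, 0 rose and 14 did not pass (8 lower adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.000685; adjusted p = 0.340 with an estimated correlation; 0.0765 on FPKM). Cxcl14 (-1.23, adjusted p = 0.0247), Ccl7 (-1.36, adjusted p = 0.0330) and Cxcl16 (-0.64, adjusted p = 0.0335) were examples besides Ccl2. The 5 became 1 without WT 165 or E4bp4-LKO 179, 2 without WT 164 or E4bp4-LKO 144 or 145, and 3 without E4bp4-LKO 143. Cxcl14 did not pass without WT 165 or any E4bp4-LKO mouse in turn (adjusted p up to 0.0772), Ccl7 without WT 164, 165 or 167 or E4bp4-LKO 143, 144 or 179 (up to 0.0997), and Cxcl16 without WT 164, WT 165 or any E4bp4-LKO mouse in turn (up to 0.0941).

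Some genes of hepatocyte-made acute phase proteins fell as well. Of 18 genes, 7 fell, 0 rose and 11 did not pass (9 lower adjusted over the list alone), with a median of -0.23. Lcn2, an iron-binding protein, fell from 190 ± 59.6 to 58.9 ± 13.3 CPM (SD, n = 4; log2 fold change -1.69, adjusted p = 0.00440), and Orm2 (-0.95, adjusted p = 0.00537), Saa1 (-0.62, adjusted p = 0.00536) and Steap4 (-0.46, adjusted p = 0.00632) fell too. Saa1 and Orm2 had fractional counts. The camera test gave an adjusted p = 0.00282, and adjusted p = 0.340 with an estimated correlation. Of 17 interferon response genes, 2 fell (Ifi44, -0.56, adjusted p = 0.0464, and Ifit2, -0.62, adjusted p = 0.0465), 0 rose and 15 did not pass (2 lower adjusted over the list alone), with a median of -0.27. The interferon list had an adjusted p = 0.00710 by camera and adjusted p = 0.508 with an estimated correlation, and it was not called by fry (0.153) or without WT 166 (0.0700, median -0.15). Its count became 0 without WT 165, WT 166 or E4bp4-LKO 144, 145 or 179 and 1 without WT 167. Ifi44 passed only without E4bp4-LKO 143 (adjusted p up to 0.132) and Ifit2 only without WT 167 or E4bp4-LKO 143 (up to 0.124).

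Other cell types of the liver did not shift as 1 body. Sinusoidal endothelial genes had a median of 0.10, which turned negative on FPKM, TPM and library totals and was -0.01 without E4bp4-LKO 143, with 0 of 14 passing in either direction (0 adjusted over the list alone). Kdr, the main VEGF receptor, measured 31.9 ± 2.05 and 44.0 ± 10.7 CPM (log2 fold change 0.46, adjusted p = 0.0593). The list was not called (adjusted p = 0.183 by camera; adjusted p = 0.811 with an estimated correlation), but it was without E4bp4-LKO 145 (0.0319, median 0.17), and Kdr passed without E4bp4-LKO 143 (log2 fold change 0.28, adjusted p = 0.0453). Of 13 cholangiocyte and ductular genes, 1 fell, 0 rose and 12 did not pass (1 lower adjusted over the list alone), with a median of -1.04. The member that fell was Spp1, which also belongs to the secreted factor and lipid-associated macrophage lists. The duct keratin Krt7 had a log2 fold change of -1.41 (adjusted p = 0.0838). WT 164 had a score of 1.29 for this list, the other WT livers reached down to -0.21, and E4bp4-LKO livers lay at -0.50 to -0.16. By camera the adjusted p was 0.0173, adjusted p = 0.599 with an estimated correlation, 0.1998 by fry, 0.280 on library totals, 0.736 on FPKM, 0.861 on TPM, 0.172 on quantile-normalized FPKM, 0.260 with a filter at 5 CPM, and 0.186 without WT 164 and 165. The median was -0.45 without WT 164 alone. Of 9 portal fibroblast, smooth muscle and mesothelial genes, 2 fell, 0 rose and 7 did not pass (5 lower adjusted over the list alone), with a median of -0.96, among them Gpx3, an extracellular peroxidase (-1.23, adjusted p = 0.00392). Its adjusted p was 0.00588 by camera, 0.0950 on library totals, and adjusted p = 0.340 with an estimated correlation. The 2 became 1 without WT 164, WT 165 or E4bp4-LKO 143, 144 or 145, and the 1 lower duct gene became 2 without WT 166 or WT 167, while 1 duct gene rose without E4bp4-LKO 179.

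Some cell-cycle genes fell in E4bp4-LKO livers. Of 17 genes, 9 fell, 0 rose and 8 did not pass (14 lower adjusted over the list alone), with a median of -0.99. The replication licensing genes Mcm5 (17 ± 4.36 against 8.07 ± 1.41 CPM, log2 fold change -1.08, adjusted p = 0.00733) and Mcm2 (-0.99, adjusted p = 0.00979) and the polymerase clamp Pcna (-0.39, adjusted p = 0.0146) fell. Cdkn1a, which belongs to the list but inhibits the cycle, fell as given above. The list had a camera adjusted p = 7.61e-08, and adjusted p = 0.340 with an estimated correlation. WT 164 had the highest score, 1.03, and E4bp4-LKO livers lay at -0.83 to -0.25. The 9 became 5 without E4bp4-LKO 144 and 2 without WT 164 and 165 together.

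Stress and immediate-early genes were lower in part. Of 13 immediate-early genes, 5 fell, 0 rose and 8 did not pass (5 lower adjusted over the list alone), with a median of -0.41. The transcription factor genes Klf6 (52.1 ± 7.80 against 22.4 ± 1.74 CPM, log2 fold change -1.22, adjusted p = 0.000248), Atf3 (-1.17, adjusted p = 0.00442) and Jun (-0.75, adjusted p = 0.00741) fell. This list had an adjusted p = 0.00110 by camera and adjusted p = 0.356 with an estimated correlation. Its median was -0.16 without E4bp4-LKO 179, -0.74 without E4bp4-LKO 145 and -0.62 without E4bp4-LKO 143, and E4bp4-LKO 179 had a score of -0.90 against -0.31 to 0.14 in the other E4bp4-LKO livers. Of 16 NRF2 and oxidative stress genes, 4 fell, 0 rose and 12 did not pass (6 lower adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.000178; adjusted p = 0.340 with an estimated correlation). The glutathione transferase Gstm3 fell from 716 ± 182 to 205 ± 53.3 CPM (log2 fold change -1.80, adjusted p = 0.00183), with fractional counts that leave the split among the Gstm copies uncertain. Nqo1, a quinone reductase, fell as well (-0.53, adjusted p = 0.0184) but did not pass without WT 165, E4bp4-LKO 144 or E4bp4-LKO 145 (up to 0.0592). The 4 became 2 without WT 165 and 1 without E4bp4-LKO 144. The list of the unfolded protein and integrated stress response was not called (median 0.16, which turned negative on TPM and library totals; adjusted p = 0.109 by camera, adjusted p = 0.439 with an estimated correlation). Xbp1 rose in it (0.51, adjusted p = 0.00625) and Atf3 fell, with 2 of 20 higher, 1 lower and 17 not passing (4 higher and 1 lower adjusted over the list alone). The 2 became 1 without WT 165, 166 or 167 or E4bp4-LKO 144 or 179, and the 1 lower became 2 without E4bp4-LKO 143.

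Most male-biased liver genes tested rose, and some female-biased ones fell. Of 17 male-biased genes, 13 rose, 0 fell and 4 did not pass (15 higher adjusted over the list alone), with a median of 1.66. Besides Hsd3b5 and Slco1a1, the coenzyme A hydrolase gene Nudt7 rose from 165 ± 18.4 to 358 ± 20.1 CPM (SD, n = 4; log2 fold change 1.12, SE 0.10, adjusted p = 0.000200), and the complement gene C8a from 358 ± 50.4 to 651 ± 37.3 CPM (log2 fold change 0.86, SE 0.11, adjusted p = 0.00193). Tested by camera, the list had an adjusted p = 1.58e-13, and adjusted p = 0.340 with an estimated correlation. Of 11 female-biased genes, 5 fell, 0 rose and 6 did not pass (5 lower adjusted over the list alone), with a median of -1.04. Examples were Cyp2b13 (2.45 ± 1.34 against 0.0866 ± 0.121 CPM, log2 fold change -4.78, adjusted p = 0.00472), which shares reads with its paralogs, and the proton pump subunit Atp6v0d2 (-1.69, adjusted p = 0.0117). This list had an adjusted p = 0.00401 by camera, 0.0820 on library totals, 0.0519 without a low-count filter, and adjusted p = 0.340 with an estimated correlation. The 5 became 3 without WT 164, WT 165, E4bp4-LKO 144 or E4bp4-LKO 179 and 1 without WT 164 and 165 together. Of 4 Y-linked genes in the sex-chromosome list, 0 passed in either direction (0 adjusted over the list alone; median 0.04, which turned negative on FPKM, TPM and library totals and without E4bp4-LKO 179 (-0.0021), and was 0.01 without WT 164, 0.07 without WT 165 or 166 and 0.08 without E4bp4-LKO 144; camera adjusted p = 0.649 and adjusted p = 0.837 with an estimated correlation). Their summed level was 123 to 134 CPM in WT and 128 to 152 CPM in E4bp4-LKO livers, and Xist had no value in the files.

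Genes of drug metabolism and bile acid handling rose in part. Of 16 xenobiotic P450 genes, 7 rose, 1 fell and 8 did not pass (11 higher and 1 lower adjusted over the list alone), with a median of 0.58. Cyp3a11, the main drug-metabolising P450 of its subfamily, rose from 3188 ± 330.5 to 9491 ± 1038 CPM (log2 fold change 1.57, SE 0.13, adjusted p = 0.000181), and Cyp2c70, which makes muricholic acids, from 212 ± 24.4 to 345 ± 48.5 CPM (log2 fold change 0.71, SE 0.12, adjusted p = 0.00638). Reads shared within the Cyp2c and Cyp3a families leave single copies uncertain. Camera gave an adjusted p = 2.47e-05, and adjusted p = 0.340 with an estimated correlation. Of 18 genes of bile acid synthesis and transport, 5 rose, 1 fell and 12 did not pass (8 higher and 1 lower adjusted over the list alone), with a median of 0.36 (camera adjusted p = 2.47e-05; adjusted p = 0.356 with an estimated correlation). The uptake transporter Slc10a1 rose from 287 ± 82.3 to 610 ± 17.5 CPM (log2 fold change 1.09, SE 0.18, adjusted p = 0.00710) and the oxysterol hydroxylase Cyp7b1 from 41.6 ± 12.3 to 106 ± 26.2 CPM (log2 fold change 1.34, SE 0.24, adjusted p = 0.0115). The efflux pump gene Abcc4 fell (-0.54, adjusted p = 0.0248). WT 164 had the lowest score for both lists. The 7 P450 genes became 2 without E4bp4-LKO 144 and 4 without WT 165 or E4bp4-LKO 179, and the lower one, Cyp2c55, named after its values were seen (log2 fold change -1.01, adjusted p = 0.04995), passed only without WT 166 or WT 167 (up to 0.136). The 5 bile acid genes became 3 without WT 165 or E4bp4-LKO 144, 145 or 179, and Abcc4 did not pass without WT 165, E4bp4-LKO 144 or E4bp4-LKO 145 (adjusted p up to 0.0761).

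**Figure D3:**
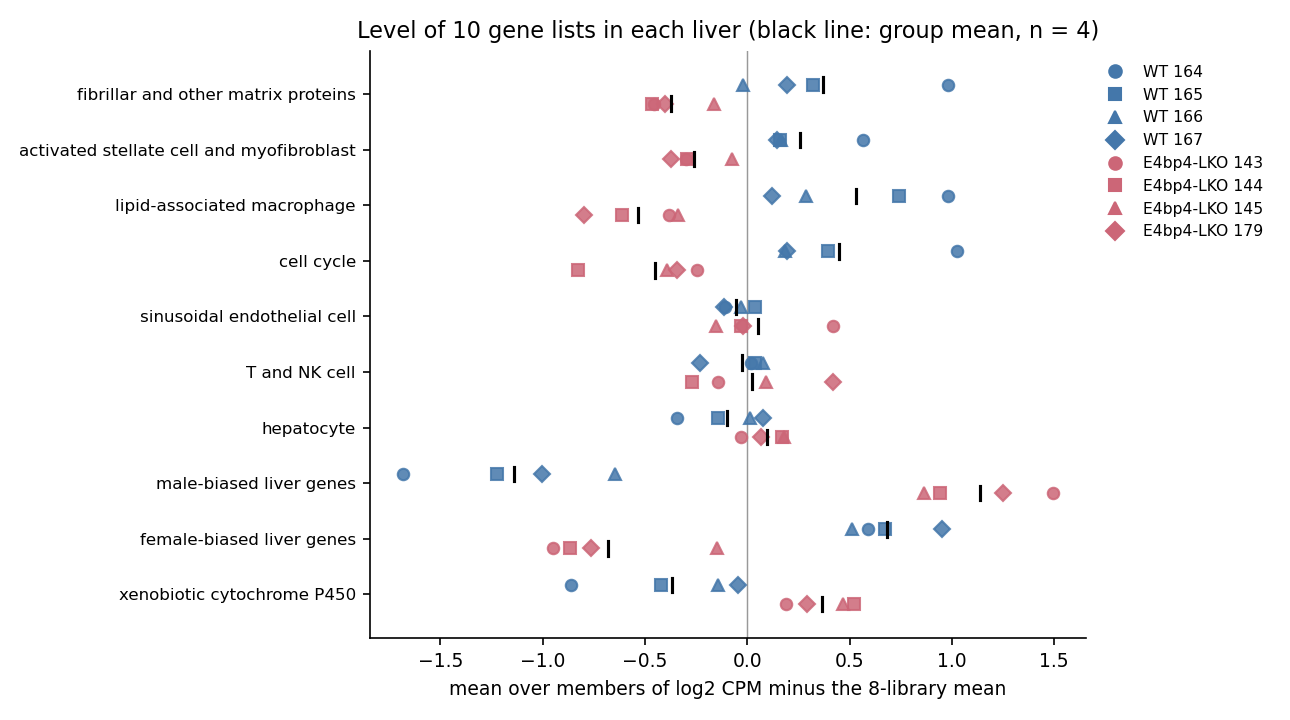
Level of 10 gene lists in each liver, as the mean over members of log2 CPM minus the mean of the 8 libraries (horizontal), with a point per library and a black line for each group mean (n = 4). Male-biased scores run from -1.68 to -0.64 in WT and from 0.86 to 1.5 in E4bp4-LKO, and WT 164 is the highest library for the matrix, lipid-associated macrophage and cell-cycle lists.

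Some genes listed as clock output through D-box elements, the DNA sites of E4BP4 itself, were higher, while binding at these sites was not tested. Of 18 genes listed for D-box elements and PAR bZIP factors, 5 rose, 0 fell and 13 did not pass (6 higher adjusted over the list alone). Their median was 0.41, and the list scores overlapped between the groups (WT -0.57 to 0.086, E4bp4-LKO -0.006 to 0.38). The carboxylesterase Ces3a rose from 998 ± 206 to 1884 ± 81.3 CPM (log2 fold change 0.92, adjusted p = 0.00537) and Ces2a from 85.8 ± 21.5 to 158 ± 23.4 CPM (log2 fold change 0.89, adjusted p = 0.0155), beside Cyp3a11, and both esterases had fractional counts. The camera test gave an adjusted p = 0.00257, fry an adjusted p = 0.0563, and the list had an adjusted p = 0.439 with an estimated correlation. Of 18 circadian clock genes, 2 rose, 0 fell and 16 did not pass (5 higher adjusted over the list alone), with a median of 0.27. The clock repressor Bhlhe41 rose from 3.33 ± 0.429 to 7.55 ± 3.03 CPM (log2 fold change 1.18, adjusted p = 0.0147), and the PAR bZIP factor Tef from 184 ± 18.7 to 232 ± 18.5 CPM (0.34, adjusted p = 0.0472). The clock list had an adjusted p = 0.0166 by camera, adjusted p = 0.426 with an estimated correlation, 0.0812 by fry, 0.0708 without E4bp4-LKO 145 and 0.0543 without E4bp4-LKO 179, and its median was 0.18 without WT 164 and 0.11 without E4bp4-LKO 145. The time of day of tissue collection is not given in the sources used here. The 5 D-box genes became 2 without WT 165 or E4bp4-LKO 144 and 3 without E4bp4-LKO 145 or 179, and 1 gene was lower without E4bp4-LKO 179. The 2 clock genes became 1 without WT 164, WT 165, E4bp4-LKO 145 or E4bp4-LKO 179. Ces2a did not pass without WT 165 or E4bp4-LKO 144 (up to 0.0515), and Tef passed only without WT 167 or E4bp4-LKO 143 (up to 0.116).

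Lipid metabolism did not shift as lists. In de novo lipogenesis, 3 of 20 genes rose, 0 fell and 17 did not pass (4 higher adjusted over the list alone), with a median of 0.00 (camera adjusted p = 0.513; adjusted p = 0.894 with an estimated correlation). Thrsp, a lipogenic regulator, rose from 444 ± 86.0 to 808 ± 142 CPM (SD, n = 4; log2 fold change 0.87, adjusted p = 0.0111). In fatty acid oxidation, 2 of 22 rose, 0 fell and 20 did not pass (2 higher adjusted over the list alone), with a median of 0.02 (camera adjusted p = 0.702; adjusted p = 0.975 with an estimated correlation). The peroxisomal gene Ehhadh rose (0.64, adjusted p = 0.0224). Both medians turned negative on FPKM, TPM, quantile-normalized FPKM and library totals. Of 18 lipid droplet and uptake genes, 1 fell (Cidec, -0.63, adjusted p = 0.0385), 0 rose and 17 did not pass (0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0969; adjusted p = 0.602 with an estimated correlation). That list was called without WT 164 (0.0105), without E4bp4-LKO 179 (0.0400), on quantile-normalized FPKM (0.0118) and with a filter at 5 CPM (0.0434). The signs and counts changed with the mouse left out. Without 1 mouse the lipogenic median ran from -0.17 (E4bp4-LKO 143 left out) to 0.09 (E4bp4-LKO 144 left out) and that of oxidation from -0.10 (WT 164 left out) to 0.11 (WT 167 left out). The 3 lipogenic genes became 1 without WT 165 or E4bp4-LKO 144, with 2 lower without E4bp4-LKO 143 and 1 lower without E4bp4-LKO 179. The 2 oxidation genes became 0 without WT 165 or E4bp4-LKO 145 or 179, 1 without E4bp4-LKO 143 or 144 and 4 without WT 167, with 1 lower without E4bp4-LKO 179. Ehhadh did not pass without WT 165 or E4bp4-LKO 145 or 179 (up to 0.0709), nor did Cidec without WT 165, 166 or 167 or E4bp4-LKO 143, 144 or 145 (up to 0.103). The lipid droplet count of 1 became 0 without WT 165, 166 or 167 or E4bp4-LKO 144 and 3 without E4bp4-LKO 179.

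Sterol and glucose metabolism did not shift as lists either. For cholesterol synthesis, 1 of 21 rose, the sterol carrier Stard4 (0.47, adjusted p = 0.0226), 0 fell and 20 did not pass (1 higher adjusted over the list alone). Its median was 0.00, its mean -0.01 and its test pointed down (camera adjusted p = 0.966; adjusted p = 0.986 with an estimated correlation). In gluconeogenesis and glycogen metabolism, 2 of 12 rose, 2 fell and 8 did not pass (2 higher and 3 lower adjusted over the list alone). The median was 0.01, the mean -0.05 and the test pointed down (camera adjusted p = 0.966; adjusted p = 0.986 with an estimated correlation). Both medians turned negative on FPKM, TPM, quantile-normalized FPKM and library totals. Without 1 mouse the cholesterol median ran from -0.12 (E4bp4-LKO 143 left out) to 0.12 (WT 164 or E4bp4-LKO 144 left out) and the gluconeogenic one from -0.08 (WT 164 left out) to 0.12 (WT 167 left out). Igfbp1, an insulin-repressed binding protein, fell from 80.0 ± 15.1 to 27.9 ± 5.44 CPM (SD, n = 4; log2 fold change -1.52, adjusted p = 0.00119). Stard4 did not pass without WT 165 or E4bp4-LKO 145 (up to 0.0645), and 1 cholesterol gene was lower without E4bp4-LKO 143. The 2 higher gluconeogenic genes became 0 without WT 165 or E4bp4-LKO 144, 145 or 179 and 1 without WT 166 or 167. The 2 lower ones became 1 without WT 164, 165 or 166 or E4bp4-LKO 143, 144 or 179.

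The hepatocyte marker list rose slightly by camera, but not under every scaling. Its median was 0.18, with 0 of 19 genes passing in either direction (0 adjusted over the list alone). The urea-cycle gene Cps1 measured 1765 ± 107 and 2417 ± 410.0 CPM (log2 fold change 0.45, adjusted p = 0.0510). By camera the adjusted p was 0.0329, and adjusted p = 0.628 with an estimated correlation. The median was -0.14 with quantile-normalized FPKM and -0.02 on TPM, and the call ended in fry (0.298), with a filter at 5 CPM (0.0580) and without WT 164 (0.177), WT 165 (0.0605), E4bp4-LKO 144 (0.0585) or E4bp4-LKO 145 (0.0870). The count of 0 higher became 1 without WT 167 or E4bp4-LKO 143, and Cps1 passed without E4bp4-LKO 143 (0.0237).

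The lists for blood and for neighbouring tissues were not called. In the blood list, 1 of 9 genes rose (Alas2, 0.51, adjusted p = 0.0355), 0 fell and 8 did not pass (1 higher adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.612; adjusted p = 0.933 with an estimated correlation), and hemoglobin genes took 0.0360% to 0.428% of counts. The blood median was 0.23 without WT 164, -1.11 without E4bp4-LKO 143, -0.59 without WT 165, -0.04 without E4bp4-LKO 144 and -0.03 without E4bp4-LKO 145. Alas2 did not pass without WT 165, WT 166, E4bp4-LKO 143 or E4bp4-LKO 179 (up to 0.0910). In the list for pancreas, adipose and gut tissue, 0 of 4 passed (1 higher and 1 lower adjusted over the list alone), with a median of -0.04, a mean of 0.76, a range of -0.18 (WT 164 left out) to 0.03 (WT 166 or E4bp4-LKO 144 left out) for the median without 1 mouse, and a test that pointed up (camera adjusted p = 0.985; adjusted p = 0.986 with an estimated correlation). Its member Cfd, the adipose gene for adipsin, measured 8.02 ± 8.91 and 89.3 ± 58.1 CPM with overlap (log2 fold change 3.50, adjusted p = 0.0754). The mitochondrially encoded list had 0 of its 9 genes in the files. Camera called 23 of the 37 tested lists, 17 lower and 6 higher, while 0 were called with an estimated correlation and 16 by fry (13 lower and 3 higher). On library totals the lower genes became 8 in the protease list, 8 in the cytokine list, 7 in the lipid droplet list, 7 in the NRF2 list, 6 in the interferon list, 4 in the portal fibroblast list, 4 in the fatty acid oxidation list and 2 each in the hepatocyte and unfolded protein lists. There, 1 gene was lower in each of the clock, lipogenesis, cholesterol and neighbouring-tissue lists, the higher genes became 0 in the matrix, secreted factor, cholesterol and blood lists, and they became 1 in the clock, gluconeogenesis and unfolded protein lists. On TPM, camera no longer called the quiescent stellate (0.121), secreted factor (0.121), Kupffer (0.253), monocyte (0.371), cytokine (0.121) and portal fibroblast (0.0658) lists, and on FPKM the first 4 of these had adjusted p of 0.0791, 0.0765, 0.119 and 0.246. Of the 35 ways to divide the 8 libraries into groups of 4, 3 called as many lists, the real one included, so the number of lists called does not set the genotypes apart from other groupings.

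**Figure D4:**
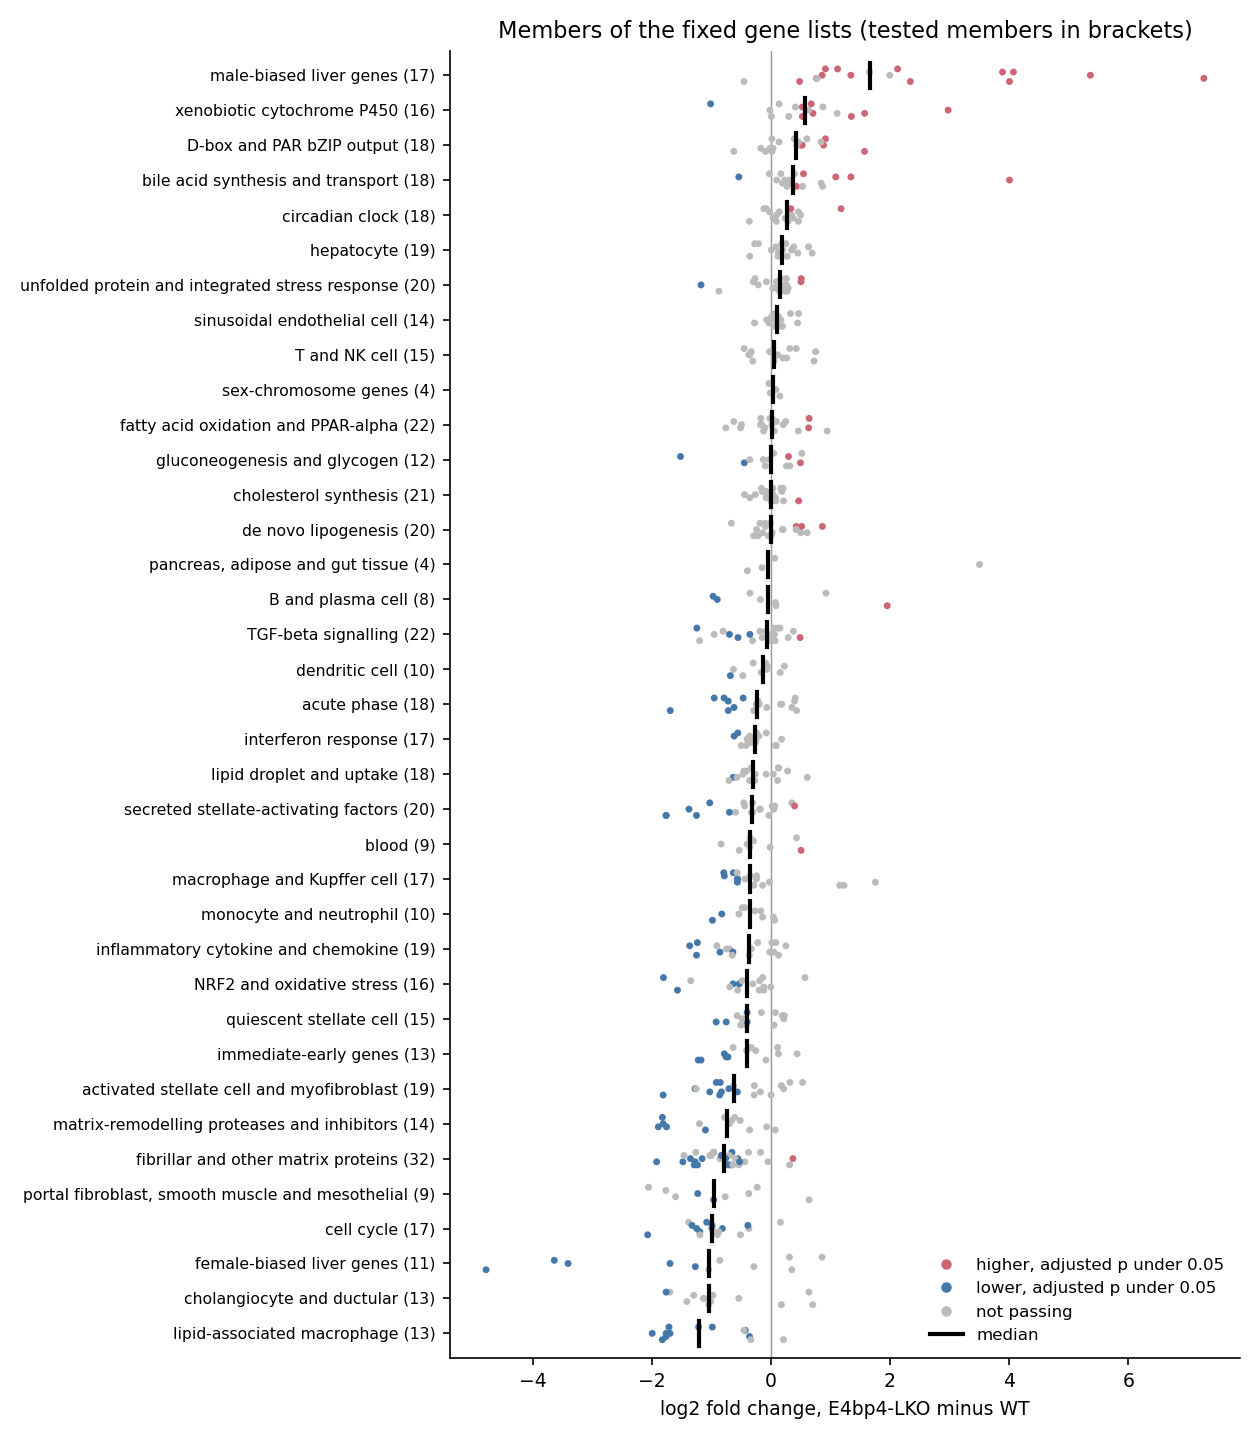
Log2 fold change of each tested member (points) of the fixed gene lists, sorted by list median (black bars), with numbers of tested members in brackets. Red and blue points passed an adjusted p of 0.05, and medians run from -1.21 for lipid-associated macrophages to 1.66 for male-biased genes.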

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

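The tests of explanations for the lower gene lists and for the sex-biased genes were chosen only after those results had been seen. So was the test of shared reads in the Nat8 family. The counts of splits were set beforehand. The rule for the test around Nfil3 was too, but Nnt and the Nat8 family, to which it was applied, were picked out after their values were seen.

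Of the 35 ways to divide the 8 libraries into groups of 4, only 1, the real one, called as many genes as the 1436 reported (highest other, 0). That is the smallest share 35 splits allow, 1 in 35, so chance is argued against for the number of genes changed but not excluded. The other splits mix the genotypes, so a real group difference widens the spread within their groups and lowers their counts. Anything else that follows the groups would give the same result. For the fixed gene lists, 3 of the 35 splits, the real one included, called as many as the 23 reported (highest other, 25). Chance cannot be excluded for that number. The other splits called 4 to 25 lists with a median of 12, so camera with the preset correlation calls lists in groupings that mix the genotypes too.

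The matrix, activated stellate cell, lipid-associated macrophage and cell-cycle lists were lower in E4bp4-LKO, with medians of -0.79, -0.62, -1.21 and -0.99, and WT 164 had the highest score for each. A lower share of all cells other than hepatocytes is argued against as the whole cause, because the sinusoidal endothelial list had a median of 0.10 (quartiles 0.02 and 0.19; -0.06 on library totals and -0.01 without E4bp4-LKO 143), though other such lists had medians below 0 too (cholangiocyte -1.04, portal fibroblast -0.96, quiescent stellate -0.40 and Kupffer -0.35). Without WT mice 164 and 165 the medians of the 4 lists were -0.47, -0.43, -0.66 and -0.61. Each median moved toward 0 but stayed below it, and in each list WT 166 and 167 scored above every E4bp4-LKO liver. WT 164 and 165 are therefore argued against as the whole source. The genes that fell went from 16, 9, 10 and 9 to 4, 5, 5 and 2. Camera still called the 4 lists (adjusted p = 5.71e-08, 1.80e-05, 1.45e-07 and 6.75e-06). Those calls decide nothing, since camera with the preset correlation also called lists in groupings that mix the genotypes. Camera with an estimated correlation was not run without WT 164 and 165. The TMM scaling could not be judged from library totals, where the median nearest to 0 was -0.81 and all 4 calls held. Leaving out TMM shifted the median log2 fold change of all genes by -0.159, which by itself lowers medians already below 0. Whether fewer cells of several of these types or less RNA per cell lowered these lists was not tested and stays open, and 0 of the 4 lists were called with an estimated correlation.

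Male-biased liver genes were higher and some female-biased ones lower in E4bp4-LKO. Female mice among the WT are argued against, because the summed Y-linked genes of the lowest library reached 81.2% of the highest. Reads shared between paralogs are argued against for the male-biased genes: of the members with whole counts in all 8 libraries (Elovl3, Cyp7b1, C6, C8a and Cyp2u1, 5 in number), 100% were called higher, against 3.81% of all genes with whole counts, although C6 passed only without WT 166 or E4bp4-LKO 145 among the fits without 1 mouse (adjusted p up to 0.102). WT mice 164 and 165 alone are argued against for the male-biased genes, as the median was 1.68 without these mice and 1.66 with them. The camera call without them (adjusted p = 3.60e-14) decides nothing, for the reason given above. Without both mice the 13 male-biased genes that rose became 7, and the 5 female-biased ones that fell became 1 (median -0.81). Neither list was called with an estimated correlation in the full data (adjusted p = 0.340 for each). The hormonal state of the mice, which may follow loss of E4bp4 or differ between the groups for another reason, stays open and was tested in the last part only through growth hormone targets. Among WT livers, the male-biased score was lowest in WT 164 (-1.68), which had the highest matrix score (0.98). It was highest in WT 166 (-0.64), which had the lowest matrix score (-0.02). Among E4bp4-LKO livers, mouse 145 had the lowest male-biased score (0.86) and the highest matrix score (-0.16), while the others differed in order. Whether the male-biased and matrix lists share a cause was not tested.

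Nnt and Nat8-family genes were higher in E4bp4-LKO and were picked out after their values were seen: Nnt, a mitochondrial transhydrogenase with whole counts, measured 86.9 ± 3.66 and 285 ± 22.0 CPM (SD, n = 4; log2 fold change 1.71, SE 0.08, adjusted p = 1.89e-06). Nat8 (2.53), Nat8f5 (2.41), Nat8f6 (3.48) and Nat8f1 (0.86) passed without each mouse in turn, and of 8 tested Nat8 copies 6 were higher and 0 lower. Reads shared between paralogs are argued against as the whole cause, because the summed level of the family was 1027 ± 128 and 1360.3 ± 98.5 CPM, a log2 difference of 0.41 without overlap (exact permutation p = 0.0286), and the 2 copies that did not pass, which make up most of that sum and of its rise, were not lower in sum (954 ± 119 and 1127 ± 81.0 CPM, against 72.2 ± 10.2 and 234 ± 23.3 CPM for the 6 that passed). A strain or substrain difference between the groups, around Nfil3, at Nnt or elsewhere, cannot be told apart from an effect of E4bp4 loss. This holds for other genes too, since strain and littermate status are not given and any such difference follows the groups. Among the 40 tested genes nearest to Nfil3 (20 on each side), 4 had changed, and 61.9% of such windows held as many or more. This gives no sign of a cluster within that window. It does not speak to DNA farther from Nfil3, on the same chromosome or elsewhere in the genome. For Nnt itself no such count was available, and its distance from Nfil3 was not examined.

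Single libraries stood far from the other 3 of their group in 18 of 340 groups tested (5.29%; 10 in WT and 8 in E4bp4-LKO), where chance gives about 1 in 20. In WT 164, Tgfb1 measured 42.3 CPM (others 30.1 to 31.9), Tgfbi 142 CPM (105 to 109), Pf4 2.92 CPM (1.37 to 1.54) and Cyp2f2 715 CPM (1099.8 to 1145). WT 165 had Rgs5 at 24.8 CPM (21.6 to 22.1) and Thrsp at 316 CPM (472 to 499.6), and WT 166 had Nat8f7 at 0.491 CPM (0 to 0.0610). In WT 167, Plaur lay at 2.83 CPM (3.54 to 3.61), Plac8 at 9.93 CPM (11.2 to 11.3) and Cyp2c70 at 248 CPM (197 to 201).

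Among E4bp4-LKO libraries, mouse 143 had Kdr at 59.96 CPM (others 37.7 to 39.6) and Ifit3 at 19.0 CPM (16.6 to 16.98), and mouse 144 had Dcn at 190.3 CPM (229 to 231). In mouse 145, Pdgfrb measured 25.8 CPM (19.1 to 20.2), Cyp2b9 10.2 CPM (1.41 to 2.28) and Bhlhe41 12.1 CPM (5.85 to 6.19). Mouse 179 had Des at 5.27 CPM (6.995 to 7.11) and C8a at 707 CPM (626 to 638). Of these, Cyp2b9 passed only without E4bp4-LKO 145 among the fits without 1 mouse (adjusted p up to 0.0956), and Kdr passed only without E4bp4-LKO 143 (adjusted p = 0.0453).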

How the results depend on the processing

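Library totals without TMM and the fit without WT 164 and 165 were chosen only after the data had been seen. Nfil3 was lower and passed under every alternative run (log2 fold change -1.57 to -1.04, adjusted p up to 0.0325). The number of genes changed, 1436 (578 higher, 858 lower), moved with several settings. DESeq2 gave 2233 (972 higher), including all 1436, and a threshold of 0.1 gave 2488 (1083 higher, 1405 lower). A 2-fold minimum, by construction stricter, left 369 (120 higher, 249 lower). Higher and lower genes numbered 257 and 1402 on FPKM, 260 and 1449 with a pseudocount of 0.1, 228 and 1971 on TPM (2199 in all), and 291 and 1660 on library totals, which by construction lack the TMM factors. Without 1 mouse the count was 506 to 1539 (235 to 608 higher, 271 to 932 lower), and without WT 164 and 165 it was 387 (182 higher, 205 lower), of which 362 were among the 1436. Fewer mice give a weaker test by construction, and other causes of these differences were not tested. Camera called 0 lists with an estimated correlation, against 23 with the preset of 0.01. A larger correlation makes camera stricter by construction. The estimates for the lists called ran from 0.035 (female-biased) to 0.61 (matrix). The hepatocyte list reversed on quantile-normalized FPKM (median -0.14, adjusted p = 0.0267), and the cause was not tested. Of 164 named genes, 111 had changed, 62 of them without each mouse in turn, while 49 lost the call without at least 1, 55 passed without WT 164 and 165, and 17 gained a call without at least 1. No paired analysis was possible because the groups share no replicate numbers, and alternatives by sex were not run because all libraries carry Y-linked transcripts. At this depth, 1.5-fold changes were called for 55.2% of genes in the simulation, so smaller changes can be missed. That simulation held 200 changed genes drawn independently, so the share may differ in these data, where 1436 genes were called.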

Other observations

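The Gene Ontology tests below, and the genes named with them, were chosen only after the gene results had been seen, while the test of growth hormone targets was not.

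Among the genes that rose, 436 features carried annotation and 4 terms were enriched. Classical complement activation held 9 of 19 tested genes (adjusted p = 4.34e-05), among them C8b, which rose from 43.4 ± 3.56 to 127 ± 18.7 CPM (SD, n = 4; log2 fold change 1.55, adjusted p = 4.63e-05) and passed without each mouse in turn. The pathway did not move as 1 body, since of the initiating genes C1ra rose (0.38, adjusted p = 0.0409) while C1qa (-0.56), C1qb (-0.63) and C1qc (-0.56) fell, the latter 3 without each mouse in turn as well. C1ra passed only without WT 167 or E4bp4-LKO 143 among those fits (adjusted p up to 0.120). That term was enriched in 4 of the 8 fits without 1 mouse. It held 2 higher genes without WT 164 or WT 165 (adjusted p = 1.0) and 3 without E4bp4-LKO 144 (0.514) or 179 (0.867), and it was not enriched on library totals (0.104), FPKM (0.107), TPM (0.0645) or quantile-normalized FPKM (0.0770). Steroid biosynthesis held 7 of 21 (adjusted p = 0.00893), with Hsd3b2 (0.89, adjusted p = 0.00181) and Hsd3b3 (0.83, adjusted p = 0.00537) beside Hsd3b5. It was not enriched without WT 165 (0.152) or E4bp4-LKO 144 (0.111), in DESeq2 (0.0758) or on quantile-normalized FPKM (0.107). The remaining 2 terms rested on Nat8 copies.

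Among the genes that fell, 678 features carried annotation and 17 terms were enriched. Collagen fibril organization held 12 of 29 (adjusted p = 0.000193), innate immune response 34 of 234 (adjusted p = 0.00698) and initiation of DNA replication 7 of 21 (adjusted p = 0.0334). The collagen term was enriched in 3 of the 8 fits without 1 mouse and not without WT 165 (0.864) or E4bp4-LKO 143 (0.444), 144 (1.0), 145 (0.220) or 179 (0.249). The innate immune term was not enriched without WT 164 (0.105), WT 165 (0.270) or E4bp4-LKO 144 (0.651), 145 (0.371) or 179 (0.327). The replication term was not enriched without WT 167 (0.111) or E4bp4-LKO 144 (0.651), 145 (0.0898) or 179 (0.155), nor in DESeq2 (0.0781), on FPKM (0.163), on TPM (0.304) or on quantile-normalized FPKM (0.0536). The epithelial keratin genes Krt8 (-0.80, adjusted p = 0.00166) and Krt18 (-0.78, adjusted p = 0.00472) fell and passed without each mouse in turn.

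Stronger growth hormone signalling through STAT5 in E4bp4-LKO livers is a candidate explanation for the male-biased genes, and it was tested on 3 other targets. Of Socs2, Cish and Igfals, 0 were called higher. Socs2 measured 8.18 ± 3.81 and 12.99 ± 2.68 CPM (SD, n = 4; log2 fold change 0.66, SE 0.30, adjusted p = 0.189), Cish 5.79 ± 2.33 and 17.98 ± 17.6 CPM (1.65, SE 0.76, adjusted p = 0.207), and Igfals 58.2 ± 17.5 and 98.1 ± 20.4 CPM (0.76, SE 0.23, adjusted p = 0.0634). The bound set beforehand, that no call would speak against the explanation, was met. It was set aside once the values were known, because it does not weigh the spread. All 3 estimates lie above 0 with spreads too wide to tell, and Igfals passed without WT 167 or E4bp4-LKO 143 (adjusted p down to 0.0323). The hypothesis therefore stays open.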
